A study of Mus musculus with 16 samples.

How the data were processed

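Poly(A) RNA was sequenced from mouse embryonic fibroblasts, connective tissue cells grown from embryos, that carried intact Usf2 (wild type, WT) or had lost it (knockout, KO). The 16 libraries form 2 experiments of 8 libraries. In the amino acid experiment WT and KO cells were kept in normal media or in media without amino acids, and in the glucose experiment in normal media or in media without glucose, with 2 libraries in each of the 8 groups. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each experiment was deposited as its own table, and differences between the experiments therefore include any difference in culture, library preparation or sequencing.

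The authors deposited raw read counts per Ensembl gene, as whole numbers that differ in their totals between libraries. STAR 2.7.10b, featureCounts 2.0.3 and DESeq2 1.38.3 are named, with the genome build GRCm38, per the submitters' processing notes. Per the labels' protocols, libraries came from a stranded TruSeq kit or from a DNBSEQ protocol that marks strand with dUTP; which experiment used which, the strand setting of the counting and the annotation release are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies, are therefore uncertain at the level of single genes. Totals were 30424659 to 31412954 counts per library in the amino acid experiment and 20329204 to 26342683 in the glucose experiment. Each table lists 55335 gene identifiers, of which 55154 matched GENCODE mouse release M21 (GRCm38), used for symbols and coordinates; the other 181 held at most 0.002% of the counts of a library. In the glucose table the names of the 4 normal media columns were also descriptions of samples of the amino acid table. Only the group was therefore taken from these names and their replicate numbers were not used, so these libraries are called a and b here.

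Before libraries were averaged, the 2 libraries of each group were compared. Their counts differed by more than sampling noise in all 8 groups, with a chi-square statistic of 2.422 to 17.802 per gene, and no pair was treated as 1 sample. With 2 against 2 libraries an exact permutation test of 1 gene cannot give a two-sided p under 0.333, so single values rest on the model fitted across all genes.

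Counts were scaled by TMM, filtered with filterByExpr at a minimum count of 10 and tested with the edgeR 4.0.16 quasi-likelihood F test with robust settings in R 4.3.3, with 1 term per group and all 8 libraries of an experiment in 1 fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit gave KO against WT in each medium, starved against normal media in each genotype, and the interaction, which is the starvation response in KO minus that in WT. The 8 normal media libraries were also fitted together, once with experiment as a batch term and once for the difference between experiments in the KO effect, and all 16 libraries for the difference between the starvation responses. Levels are given as CPM, counts scaled to a common library total after TMM, mean ± SD over 2 libraries, and log2 fold changes with their standard error (SE).

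Before the data were examined, 43 lists holding 1019 gene entries were fixed, covering lysosome, autophagy, nutrient, stress, growth and inflammatory themes and markers of other cell types, together with the comparisons, the alternatives and the rule for the genes named. Lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with a correlation estimated per list. The counts of members are given from the test over all genes and, where stated, adjusted over the list alone. Named genes are Usf2, Usf1, Tfeb, Tfe3 and Mitf in genotype comparisons; up to 6 called genes per direction with the greatest change among genes of at least 5 CPM whose libraries did not overlap, leaving out predicted gene models; up to 4 members with the smallest adjusted p of the 6 lysosome and autophagy lists and of each called list; and the fixed genes Sqstm1, Map1lc3b, Gabarapl1, Ctsd, Lamp1 and Mcoln1, with Asns, Chac1, Trib3 and Ddit3 for amino acids and Txnip, Arrdc4, Hspa5 and Ddit3 for glucose. The text prints a subset of these in that order, and 1 gene that the rule names is not reported here. A fold change against a group with 0 counts is given as a lower bound against a floor of 3 counts over the group, and against 1 to 3 counts as a ratio with its 95% counting interval. Intervals and floors cover counting error only.

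Alternatives were DESeq2 size factors, upper quartile scaling, no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block in the amino acid experiment, only the 4 libraries compared, and leaving out each library in turn; offsets for GC content and gene length were added after the data were seen. The tests were tried on simulated counts with known changes. For KO against WT in normal media of the amino acid experiment (15145 genes), 10% of the genes changed 1.25-fold, 62% of those changed 1.5-fold, 59.2% of those changed 2-fold and 93.8% of those changed 4-fold were recovered, with 12 false calls. For the same comparison of the glucose experiment (13527 genes) these shares were 46.9%, 68%, 92% and 95.7%, with 7 false calls. The simulated interaction recovered 54.3% of 2-fold changes in the amino acid experiment (15108 genes, 4 false calls) and 84% in the glucose experiment (13521 genes, 11 false calls).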

Results

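The data set asks what Usf2, a basic helix-loop-helix leucine zipper transcription factor that binds E-box sequences, does in the control of autophagy and lysosome genes. Autophagy delivers parts of the cytoplasm to the lysosome, the acidic compartment in which hydrolases break them down. WT and KO fibroblasts were compared in normal media and after amino acid or glucose starvation, with 2 libraries per group and 20329204 to 31412954 counts per library. In the amino acid experiment the first principal component held 57.5% of the variance and separated the media, and the second held 32% and separated the genotypes. In the glucose experiment these components held 50.8% and 39%.

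Usf2 (ENSMUSG00000058239, GRCm38 chromosome 7, 30945248 to 30956803, minus strand) was lower in KO in each of the 4 comparisons of genotypes. In normal media of the amino acid experiment Usf2 stood at 34.2 ± 1.61 CPM in WT and 15.5 ± 0.845 CPM in KO (SD, n = 2), a log2 fold change of -1.14 ± 0.11 (SE, adjusted p = 3.53e-06) that left 45.3% of the WT level. Under amino acid starvation the levels were 37.7 ± 2.51 and 17.8 ± 0.217 CPM, under normal media of the glucose experiment 36.2 ± 1.70 and 15.2 ± 0.527 CPM, and under glucose starvation 55.1 ± 4.44 and 19.96 ± 1.56 CPM (SD, n = 2 each). Counts per gene do not show which part of the Usf2 transcript the remaining reads came from. Among related factors in normal media, Tfeb, a main activator of lysosome genes, differed by -0.11 ± 0.12 and -0.09 ± 0.09 on the log2 scale in the amino acid and glucose experiments (adjusted p = 0.519 and 0.376). Usf1, a paralogue of Usf2, stood at 28.5 ± 0.181 CPM in WT and 25.3 ± 1.35 CPM in KO in the glucose experiment (SD, n = 2). In the amino acid experiment Usf1 differed by -0.03 ± 0.10 on the log2 scale (SE, adjusted p = 0.842). Tfe3 differed there by -0.23 ± 0.09 (SE, adjusted p = 0.0484), a call lost under upper quartile scaling (adjusted p = 0.0819) and with most other alternatives; without WT normal media replicate 2 the value was -0.09 (adjusted p = 0.492). Mitf, of the same family as Tfeb, was higher in KO by 0.89 ± 0.17 under amino acid starvation and by 0.94 ± 0.21 in normal media of the glucose experiment (SE, adjusted p = 0.000796 and 0.00071). In normal media of the amino acid experiment Mitf differed by 0.48 ± 0.18 (SE, adjusted p = 0.0444), a call lost with the DESeq2 Wald test (adjusted p = 0.124). It was also lost without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 of that medium (adjusted p = 0.112, 0.103, 0.08 and 0.155).

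In normal media of the amino acid experiment, genes of the lysosome were higher in KO cells. Ctsd, which encodes the lysosomal protease cathepsin D (chromosome 7, 142375911 to 142388038), stood at 276 ± 55.3 CPM in WT and 1171 ± 89.9 CPM in KO (SD, n = 2), a log2 fold change of 2.09 ± 0.12 (SE, adjusted p = 5.04e-08). Lamp1, an abundant lysosomal membrane protein, was higher by 1.39 ± 0.09 and Mcoln1, a lysosomal calcium channel, by 1.28 ± 0.09 (SE). Map1lc3b, whose product LC3B is conjugated to autophagosome membranes, stood at 156 ± 15.1 CPM in WT and 359 ± 0.199 CPM in KO (SD, n = 2). Ctsz, encoding cathepsin Z, went the other way, with a log2 fold change of -5.53 ± 0.20 (SE).

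Of 48 measured lysosomal hydrolases 34 were higher in KO, 6 lower and 8 not called (35 and 6 adjusted over the list alone; camera adjusted p = 7.54e-07). Of 36 lysosomal membrane proteins 18 were higher and 4 lower, the same counts as adjusted over the list alone (adjusted p = 0.000622). Of 19 subunits of the v-ATPase, the proton pump that acidifies the lysosome, 14 were higher and 1 lower, again as adjusted over the list alone (adjusted p = 0.000393). With an estimated correlation the adjusted p of these 3 lists was 0.655. In the autophagy conjugation list, which holds the enzymes and substrates that attach LC3-type proteins to membranes, 10 of 16 genes were higher and 0 lower. Among autophagy receptors and fusion factors 13 of 27 were higher and 4 lower. Both counts were the same as adjusted over the list alone (adjusted p = 0.0036 and 0.00782; adjusted p = 0.515 with an estimated correlation for both). Autophagy initiation genes were split, with 6 of 22 higher and 6 lower (7 and 7 adjusted over the list alone; adjusted p = 0.933, and 0.968 with an estimated correlation), and the balance became 7 higher and 5 lower under upper quartile scaling.

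Genes of dividing cells were lower in the same KO cells. All 32 measured mitosis genes were called lower, as they were adjusted over the list alone, with a median log2 fold change of -1.22 (adjusted p = 4.78e-11). Of the DNA replication genes 25 of 34 were lower and 0 higher (28 lower adjusted over the list alone; adjusted p = 1.33e-06). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, fell by 1.37 ± 0.11 and Pcna, the replication clamp, by 1.11 ± 0.11 on the log2 scale (SE). With an estimated correlation the adjusted p was 0.755 for mitosis and 0.769 for replication. The interferon response list had 18 of 24 genes lower and 1 higher (18 and 2 adjusted over the list alone; adjusted p = 7.74e-06; adjusted p = 0.554 with an estimated correlation). In the epithelial list 3 of 5 markers were lower in the same comparison, as adjusted over the list alone (adjusted p = 0.0587, and 0.755 with an estimated correlation). Only 3 members of this list were over 1 CPM in WT.

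Across 15650 genes tested in this comparison 6544 were called, 3176 higher and 3368 lower in KO. Without KO normal media replicate 1 the count was 4274. Heph, a ferroxidase of iron export, had the greatest rise among called genes of at least 5 CPM, at 5.31 ± 0.23 on the log2 scale (SE), followed by Tppp at 4.97 ± 0.30. Hspb1, a small heat shock protein (chromosome 5, 135887919 to 135889563), had 3308 counts over the WT libraries and 1 over the KO libraries, a ratio of 3290 (95% counting interval 589 to 130000), and Prdx4, an ER peroxiredoxin, had 2738 against 1.

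**Figure D1:**
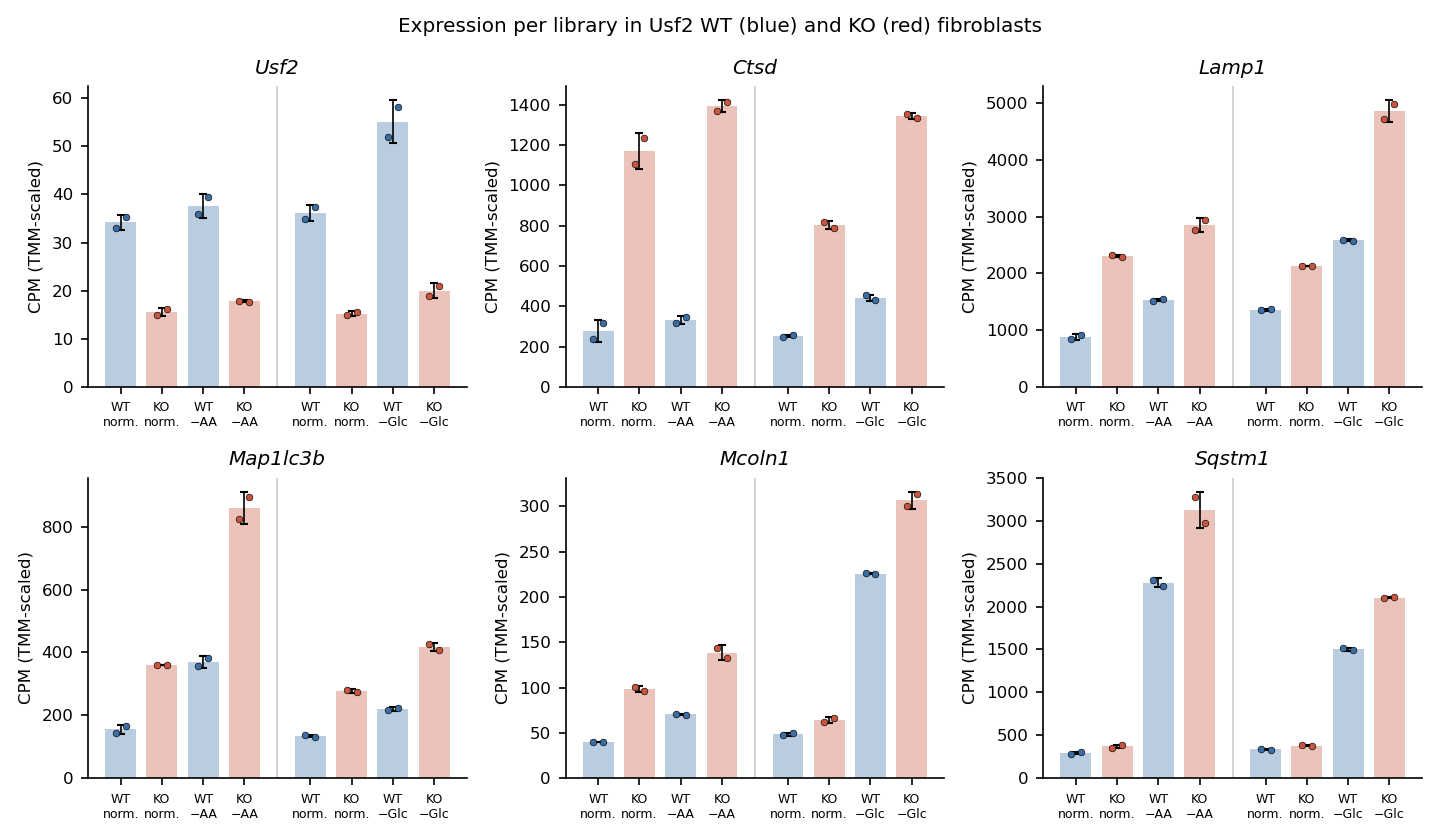
TMM-scaled CPM (y axis, from 0) of Usf2 and 5 lysosome or autophagy genes in each group (x axis; norm., normal media; −AA, without amino acids; −Glc, without glucose), amino acid experiment left of the grey line and glucose experiment right. Bars are means of 2 libraries, points the libraries and error bars the SD; Ctsd in normal media stands at 1171 CPM in KO against 276 CPM in WT in the amino acid experiment.

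The glucose experiment repeated the genotype comparison in normal media. There the mitochondrial genes held 1.49% and 1.61% of the counts of the WT libraries and 2.31% and 2.4% of those of the KO libraries, the 10 most abundant genes 5.66% and 5.53% against 6.78% and 6.77%, and 19462 and 19747 genes were detected against 18795 and 18852. In the amino acid experiment the mitochondrial share was 2.16% and 2.39% in WT and 2.7% and 2.49% in KO. The 10 most abundant genes held 5.81% and 6.44% there against 6.82% and 6.73%, and 21776 and 21724 genes were detected against 21293 and 21283. Of 13 mitochondrially encoded mRNAs 6 were higher in KO and 1 lower in the glucose experiment, as adjusted over the list alone, and the list was not called (adjusted p = 0.0518, and 0.604 with an estimated correlation). Ctsd was at 251 ± 5.15 CPM in WT and 801 ± 20.5 CPM in KO (SD, n = 2), a log2 fold change of 1.67 ± 0.06 (SE, adjusted p = 2.33e-16), and Lamp1 was higher by 0.65 ± 0.06, Mcoln1 by 0.40 ± 0.06 and Map1lc3b by 1.04 ± 0.05 (SE). Of the 48 hydrolases 29 were higher and 7 lower (29 and 8 adjusted over the list alone; adjusted p = 0.00917, and adjusted p = 0.604 with an estimated correlation). Of 36 membrane proteins 20 were higher and 8 lower (21 and 8 adjusted over the list alone; adjusted p = 0.0267), of 19 v-ATPase subunits 12 and 1 (adjusted p = 0.0113) and of 16 conjugation genes 8 and 0 (adjusted p = 0.012), the last 2 as adjusted over the list alone; with an estimated correlation the adjusted p was 0.596 for each. The v-ATPase list had a median of 0.21 and a mean of -0.002, because Atp6v0e2 stood at -5.29 ± 0.33 (SE). The call of the membrane protein list was lost without WT normal media library a (adjusted p = 0.0653). Receptors and fusion factors were higher in 14 of 27 cases and lower in 5 (14 and 6 adjusted over the list alone). This list was not called (adjusted p = 0.0842, and 0.604 with an estimated correlation), but was without WT normal media library b (adjusted p = 0.025). Gabarapl1, another LC3-type gene, was at 108 ± 1.51 CPM in WT and 111 ± 3.49 CPM in KO (SD, n = 2).

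Targets of p53, the DNA damage response factor, were higher in KO in this experiment: 19 of 22 were higher and 1 lower (19 and 2 adjusted over the list alone; adjusted p = 5.99e-07, and adjusted p = 0.596 with an estimated correlation). Phlda3 was higher by 1.16 ± 0.06 and Ccng1 by 1.05 ± 0.06 on the log2 scale (SE). All 5 measured epithelial markers were lower, as adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.596 with an estimated correlation). Only 2 members of this list were over 1 CPM in WT. Krt19, a keratin, fell by 3.78 ± 0.09 (SE). Of the 32 mitosis genes 19 were higher and 4 lower, and the list was not called (the same counts adjusted over the list alone; adjusted p = 0.0584, and 0.604 with an estimated correlation). Of 13966 genes tested 7331 were called, 3718 higher and 3613 lower in KO, against 4708 and 3171 with offsets for GC content and gene length. The interferon response list, lower in KO in the amino acid experiment, had 6 of 11 measured genes higher and 3 lower here (6 and 4 adjusted over the list alone) and was not called (median 0.509; adjusted p = 0.481, and 0.655 with an estimated correlation). Stmn2, a tubulin-binding protein (chromosome 3, 8509360 to 8561606), had 3793 counts over the WT libraries and 0 in KO, at least 1330-fold lower.

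**Figure D2:**
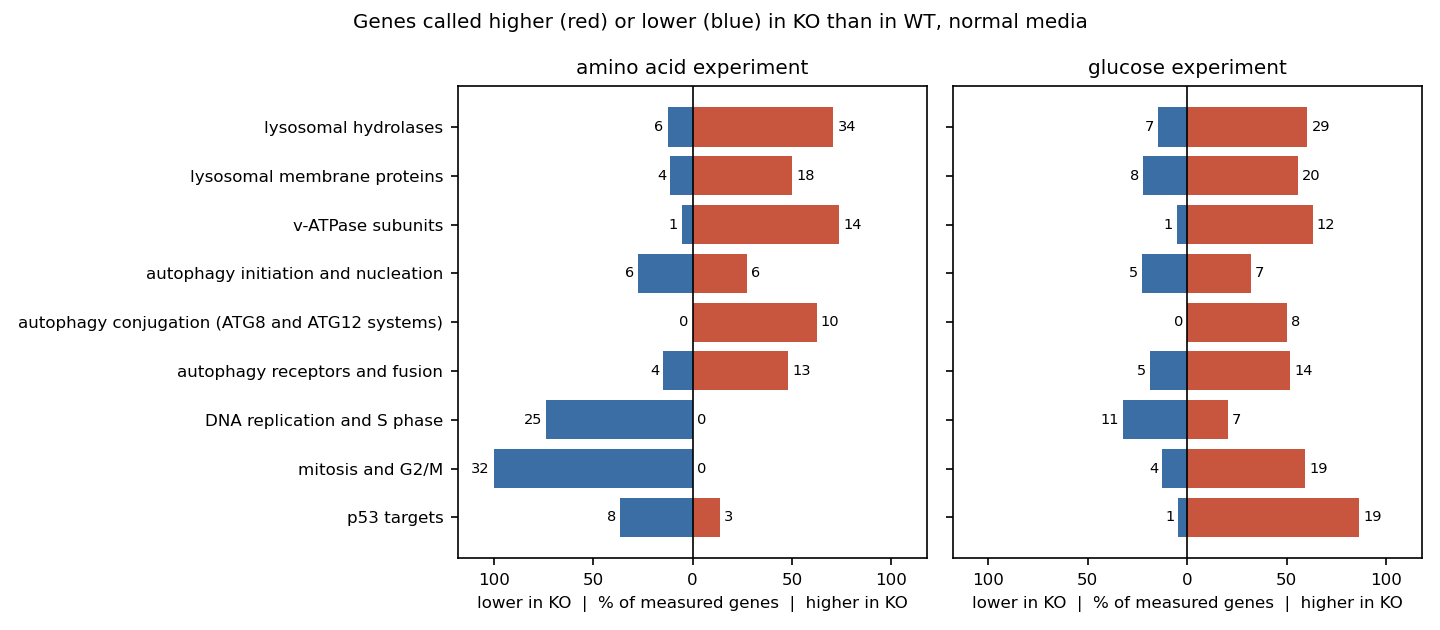
Members of 9 gene lists called higher (red, to the right) or lower (blue, to the left) in KO than in WT in normal media, as percent of the measured members (x axis), with the number of genes at each bar. Hydrolases have 34 genes higher in the amino acid experiment and 29 in the glucose experiment, and mitosis genes have 32 lower in the former and 4 in the latter.

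The KO effects of the experiments share no library. Over 13562 genes their log2 fold changes correlated at Pearson r = 0.755 and Spearman rho = 0.562, a correlation across genes, which are not independent replicates. Of these genes 1714 were higher in both experiments against 739 expected from independent lists, and 1844 lower in both against 807, while 362 were called in opposite directions. With experiment as a batch term 6445 of 15013 genes were called, 3312 higher and 3133 lower in KO. There 30 of 48 hydrolases were higher and 5 lower, as adjusted over the list alone (adjusted p = 9.66e-05, and adjusted p = 0.878 with an estimated correlation), with Ctsd at 1.88 ± 0.11 and Map1lc3b at 1.13 ± 0.07 (SE).

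The difference between the experiments was itself tested. All 32 mitosis genes had a lower KO effect in the amino acid experiment, as adjusted over the list alone, with a median difference of -1.36 (adjusted p = 1.74e-18, and adjusted p = 0.724 with an estimated correlation). The interferon response list was also called in the difference, with a lower KO effect in the amino acid experiment in 5 of 23 genes and a higher one in 0, as adjusted over the list alone (adjusted p = 4e-07, and adjusted p = 0.156 with an estimated correlation). Fewer of its members passed the count filter in the glucose experiment alone than in this joint fit. For the others the KO effect was hardly measured there, so this call rests in part on genes with few counts. A lower effect was also seen in 17 of 22 p53 targets (18 adjusted over the list alone; adjusted p = 1.06e-10, and adjusted p = 0.507 with an estimated correlation). Among hydrolases 13 of 48 had a higher KO effect in the amino acid experiment and 1 a lower one (22 and 2 adjusted over the list alone; adjusted p = 1.93e-06, and adjusted p = 0.76 with an estimated correlation). Mcoln1 differed by 0.88 ± 0.12 and Gabarapl1 by 0.79 ± 0.12 on the log2 scale (SE). In all, 2434 of 15013 genes differed, 1039 with a higher effect in the amino acid experiment and 1395 with a lower one. With the alternatives that keep all libraries the count lay between 1983 and 3330. The count was 1423 without glucose experiment WT normal media library b, 1311 without KO normal media library a and 1491 without KO normal media library b.

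Under amino acid starvation, WT cells raised the targets of ATF4, the transcription factor of the amino acid response. All 36 measured genes rose, as they did adjusted over the list alone, with a median of 2.23 on the log2 scale (adjusted p = 9.18e-17, and adjusted p = 0.093 with an estimated correlation). Asns, asparagine synthetase, rose from 162 ± 9.25 to 756 ± 53 CPM (SD, n = 2) and Chac1, a glutathione-degrading enzyme, rose by 3.56 ± 0.12 (SE). All 24 cholesterol synthesis genes fell, also adjusted over the list alone, with a median of -2.50 (adjusted p = 9.2e-10, and adjusted p = 0.546 with an estimated correlation). Sqle, squalene epoxidase, fell by 3.18 ± 0.13 (SE). Of 74 nuclear genes of oxidative phosphorylation 61 fell and 0 rose, as adjusted over the list alone (adjusted p = 4.8e-10, and adjusted p = 0.539 with an estimated correlation). In these WT libraries the mitochondrial share moved from 2.16% and 2.39% to 1.7% and 1.71% of the counts.

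The autophagy receptor Sqstm1, which encodes p62, rose in WT from 294 ± 13.1 to 2276 ± 53.5 CPM (SD, n = 2) and Gabarapl1 rose by 1.99 ± 0.10 on the log2 scale (SE). Receptors and fusion factors rose in 19 of 27 cases and fell in 6, as adjusted over the list alone (adjusted p = 0.00244, and adjusted p = 0.35 with an estimated correlation). v-ATPase subunits rose in 14 of 19 cases and fell in 4, as adjusted over the list alone (adjusted p = 0.0156, and adjusted p = 0.578 with an estimated correlation). Hydrolases went both ways, with 10 of 48 rising and 20 falling (10 and 19 adjusted over the list alone; adjusted p = 0.227, and 0.824 with an estimated correlation). Ctsd stood at 276 ± 55.3 CPM before and 330 ± 20.2 CPM after starvation (SD, n = 2; adjusted p = 0.0702). Ctsd was called higher without WT normal media replicate 2 (0.53 on the log2 scale, adjusted p = 0.000823) and with DESeq2 size factors (adjusted p = 0.0479). Of 15650 genes 10272 were called in WT, 4907 higher and 5365 lower.

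In KO cells under amino acid starvation all 36 ATF4 targets rose, as adjusted over the list alone (adjusted p = 8.62e-16, and adjusted p = 0.104 with an estimated correlation), and Sqstm1 rose by 3.07 ± 0.09 (SE). Ribosome biogenesis genes rose in 32 of 34 cases with 0 falling, as adjusted over the list alone (adjusted p = 2.31e-09), and mitosis genes fell in 27 of 32 cases with 1 rising, as adjusted over the list alone (adjusted p = 0.000274); with an estimated correlation the adjusted p was 0.675 and 0.794. In KO 10480 genes were called, 49.9% of them higher, against 38.6% higher under upper quartile scaling, which moved the median of all genes from -0.02 to -0.24 on the log2 scale. The responses of WT and KO correlated across genes at Pearson r = 0.824.

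The mitochondrial share of counts was 1.7% and 1.71% in the starved WT and 2.03% and 1.88% in the starved KO libraries of the amino acid experiment, and 21978 and 21995 genes were detected against 20582 and 20661. Between genotypes under amino acid starvation, Ctsd was higher in KO by 2.08 ± 0.12, Map1lc3b by 1.22 ± 0.09, Lamp1 by 0.90 ± 0.08 and Sqstm1 by 0.46 ± 0.09 on the log2 scale (SE). Hydrolases were higher in 33 of 48 cases and lower in 5, as adjusted over the list alone (adjusted p = 2.19e-06, and adjusted p = 0.535 with an estimated correlation). Conjugation genes were higher in 12 of 16 cases and lower in 0, as adjusted over the list alone (adjusted p = 0.00301, and adjusted p = 0.319 with an estimated correlation). All 32 mitosis genes were lower, also adjusted over the list alone (adjusted p = 3.67e-15, and adjusted p = 0.535 with an estimated correlation). In the same comparison 4 of 5 epithelial markers were lower, as adjusted over the list alone (adjusted p = 0.00301, and adjusted p = 0.535 with an estimated correlation). Of 6585 called genes 56.1% were higher in KO, against 44.5% under upper quartile scaling.

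The interaction tested whether the amino acid response differed between genotypes. No lysosome or autophagy list was called: for hydrolases 4 of 48 genes had a higher response in KO and 2 a lower one (7 and 3 adjusted over the list alone; adjusted p = 0.875, and 0.978 with an estimated correlation), and their median of 0.04 changed sign under other scalings, to -0.004 with DESeq2 size factors and -0.09 with upper quartile scaling. Map1lc3b differed by 0.01 ± 0.13 and Sqstm1 by 0.12 ± 0.12 on the log2 scale (SE; adjusted p = 0.973 and 0.598). Ribosome biogenesis genes had a higher response in KO in 17 of 34 cases and a lower one in 0 (29 and 0 adjusted over the list alone; adjusted p = 1.89e-09, and adjusted p = 0.813 with an estimated correlation), against 13 higher with DESeq2 size factors and 7 with upper quartile scaling. Their median log2 response was 0.53 in WT and 0.92 in KO. Their median in KO against WT was -0.32 in normal media and 0.14 under starvation, so a lower KO level before starvation is part of this difference. Atf3, a stress-induced factor, rose more in KO by 1.74 ± 0.17 (SE). Of 1407 genes called 68.3% had a higher response in KO, against 42.2% under upper quartile scaling, which moved the median of all genes from 0.06 to -0.06. With the replicate number as a block 2668 genes were called. The count was 621 without WT normal media replicate 2, 304 without KO normal media replicate 1, 780 without KO normal media replicate 2, 565 without KO starved replicate 1 and 616 without KO starved replicate 2.

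Under glucose starvation, lysosome genes of WT cells rose together. In the WT libraries the mitochondrial share moved from 1.49% and 1.61% to 2.04% and 2.06% of the counts, and that of the 10 most abundant genes from 5.66% and 5.53% to 7.39% and 7.6%. Mcoln1 rose from 48.5 ± 1.73 to 226 ± 0.702 CPM and Sqstm1 from 336 ± 7.79 to 1501 ± 15.3 CPM (SD, n = 2), and Lamp1 rose by 0.93 ± 0.06 and Ctsd by 0.81 ± 0.06 on the log2 scale (SE). Of 48 hydrolases 37 rose and 6 fell, as adjusted over the list alone (adjusted p = 8.52e-08, and adjusted p = 0.167 with an estimated correlation). Membrane proteins rose in 26 of 36 cases with 7 falling (28 and 8 adjusted over the list alone; adjusted p = 2.74e-05), v-ATPase subunits in 15 of 19 with 2 falling (adjusted p = 0.000187) and receptors and fusion factors in 19 of 27 with 1 falling (adjusted p = 1.14e-05), the last 2 as adjusted over the list alone; with an estimated correlation the adjusted p was 0.146 for each. Txnip, an inhibitor of glucose uptake induced by glucose, fell by 5.95 ± 0.26 (SE).

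All 36 ATF4 targets also rose in WT, as adjusted over the list alone (adjusted p = 2.33e-17). Similarly 17 of 18 targets of the hypoxia factor HIF rose with 0 falling, as adjusted over the list alone (median 1.91; adjusted p = 4.94e-09). Ndrg1 rose by 3.58 ± 0.06 and Vegfa by 2.58 ± 0.06 (SE). All 32 mitosis genes fell, also adjusted over the list alone, with a median of -1.63 (adjusted p = 4.74e-16). With an estimated correlation the adjusted p of these 3 lists was 0.0736. Of 13966 genes 9161 were called in WT, 4580 higher and 4581 lower.

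In KO cells glucose starvation raised Mcoln1 by 2.26 ± 0.06 and Sqstm1 by 2.46 ± 0.06 (SE). Hydrolases rose in 31 of 48 cases and fell in 6, as adjusted over the list alone (adjusted p = 1.24e-05, and adjusted p = 0.24 with an estimated correlation). HIF targets rose in 12 of 18 cases and fell in 3 (adjusted p = 0.00284, and adjusted p = 0.161 with an estimated correlation). p53 targets fell in 18 of 22 cases and rose in 2 (adjusted p = 4.94e-05, and adjusted p = 0.24 with an estimated correlation), both as adjusted over the list alone. In KO 9176 genes were called, 4653 higher and 4523 lower.

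Between genotypes under glucose starvation, Ctsd was higher in KO by 1.61 ± 0.06, Lamp1 by 0.91 ± 0.06, Map1lc3b by 0.92 ± 0.05 and Sqstm1 by 0.49 ± 0.05 (SE). Hydrolases were higher in 28 of 48 cases and lower in 7, as adjusted over the list alone (adjusted p = 0.00411, and adjusted p = 0.444 with an estimated correlation). HIF targets were lower in 16 of 18 cases and higher in 1, as adjusted over the list alone (adjusted p = 5.97e-07, and adjusted p = 0.0704 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.77 ± 0.07 and Bnip3, a mitophagy receptor, by 1.71 ± 0.07 in KO against WT (SE). Of 5 epithelial markers 4 were lower, as adjusted over the list alone (adjusted p = 0.00846, and adjusted p = 0.244 with an estimated correlation). Counts were low for some: Krt7 had 38 over the WT libraries and 0 over the KO libraries, and Krt18 18 and 0. Mitosis genes were lower in KO in 20 of 32 cases and higher in 1 (21 and 2 adjusted over the list alone; adjusted p = 0.000248, and adjusted p = 0.244 with an estimated correlation). The mitochondrial share of counts was 2.04% and 2.06% in the starved WT and 2.63% and 2.6% in the starved KO libraries, the 10 most abundant genes held 7.39% and 7.6% against 8.95% and 9.11%, and 19694 and 19772 genes were detected against 18405 and 18000. Of 7787 called genes 4036 were higher and 3751 lower in KO.

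No lysosome or autophagy list was called in the interaction of the glucose experiment, while other lists were. HIF targets had a lower response in KO in 15 of 18 cases and a higher one in 0 (17 and 0 adjusted over the list alone), with a median difference of -1.04 (adjusted p = 2.91e-13, and adjusted p = 0.0404 with an estimated correlation), the only list call of the 2 interactions that held with an estimated correlation. Bnip3 differed by -1.93 ± 0.11, Pdk1 by -1.92 ± 0.12 and Slc2a1, the glucose transporter GLUT1, by -0.95 ± 0.07 on the log2 scale (SE). Glycolysis genes had a lower response in 12 of 21 cases and a higher one in 3 (16 and 4 adjusted over the list alone; adjusted p = 1.93e-06, and adjusted p = 0.114 with an estimated correlation). Mitosis genes had a lower response in 24 of 32 cases and a higher one in 0 (30 and 0 adjusted over the list alone; adjusted p = 8.68e-13, and adjusted p = 0.111 with an estimated correlation). Hydrolases had 9 of 48 higher and 7 lower responses (10 and 10 adjusted over the list alone; adjusted p = 0.862, and 0.919 with an estimated correlation), and Mcoln1 differed by 0.04 ± 0.08 (SE; adjusted p = 0.787). In all 3074 genes were called, 1541 higher and 1533 lower, and 1964 with the DESeq2 Wald test.

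**Figure D3:**
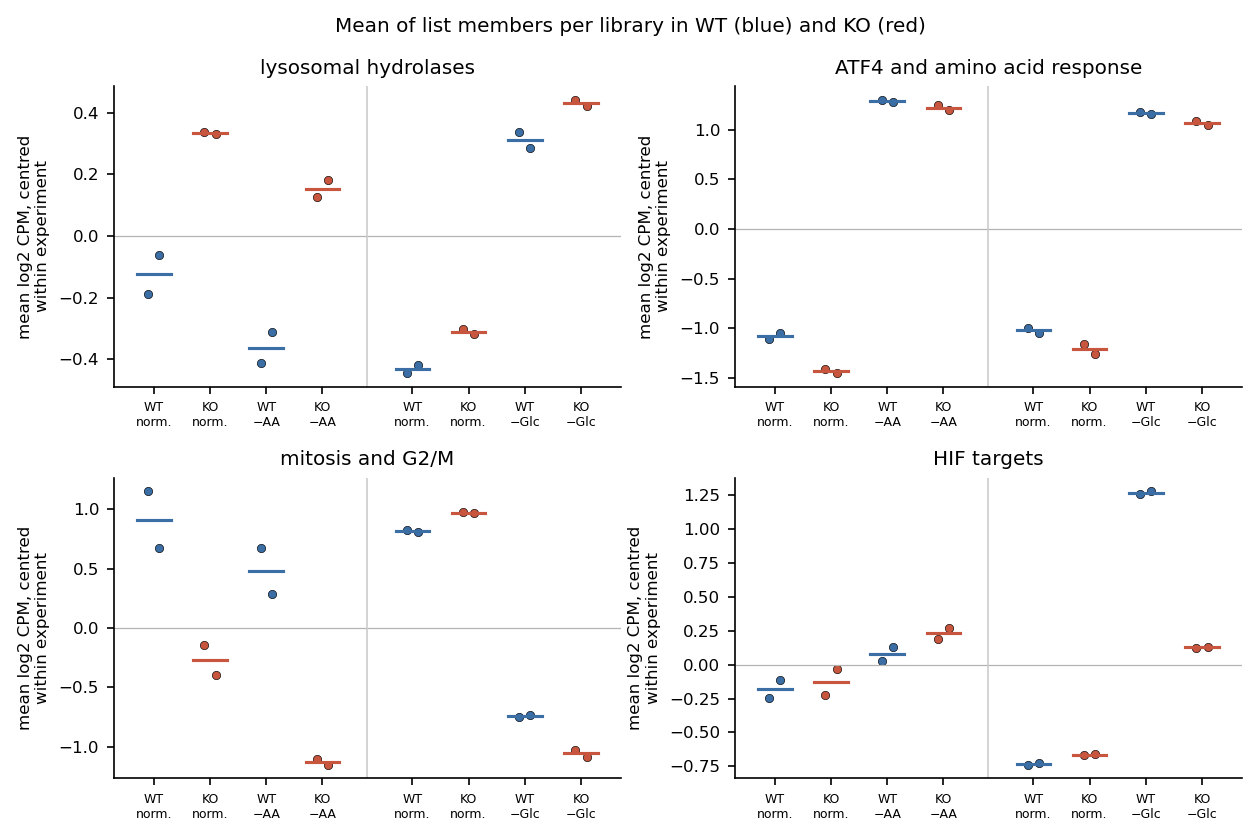
Mean log2 CPM of the members of 4 lists in each library, centred within an experiment (y axis), by group (x axis; abbreviations as in the plot of CPM per library); points are libraries and lines the means of 2. HIF targets stand at 1.259 and 1.28 in the glucose-starved WT libraries and at 0.125 and 0.129 in the glucose-starved KO libraries.

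The starvation responses differed from each other. In WT 8717 of 16121 genes had different responses to amino acid and glucose starvation, 4443 with a higher response to amino acid starvation and 4274 with a lower one, and in KO 8778 had. Hydrolases had a lower response to amino acid starvation in 41 of 48 cases in WT and a higher one in 2, as adjusted over the list alone (adjusted p = 1.59e-10, and adjusted p = 0.293 with an estimated correlation). Mcoln1 differed by -1.37 ± 0.10 and Gabarapl1 by 1.75 ± 0.07 in WT (SE). Each starvation medium was used in 1 experiment, so medium and experiment cannot be told apart here.

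The KO effect in normal media was also set against the WT starvation response of the other experiment, which shares no library with it: Pearson r across genes was 0.069 for the amino acid experiment's KO effect and -0.082 for that of the glucose experiment, and Spearman rho 0.151 and -0.172. The former KO effect and response were both higher for 1156 genes (895 expected from independent lists) and both lower for 1441 (1045 expected), and went opposite ways for 722 (905 expected) and 859 (1034 expected). The latter were both higher for 852 (1128 expected) and both lower for 1005 (1297 expected), while 1823 (1373 expected) had a higher KO effect and a lower response and 1409 (1065 expected) the reverse. Within an experiment, where both use the WT normal media libraries, r was 0.032 and 0.027 and the covariance 0.043 and 0.027, while 20 simulations without any effect gave a mean r of 0.497 and 0.532 and a mean covariance of 0.065 and 0.042. Genes higher in both numbered 844 in the amino acid experiment (996 expected from independent lists) and 1328 in the glucose experiment (1219 expected). Genes lower in both numbered 1142 (1155 expected) and 1321 (1185 expected). Both covariances within an experiment lay under the simulated mean. A split of the 2 WT normal media libraries would leave 1 in each part and was not made, so part of any excess may come from the shared controls.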

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

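The tests for fewer dividing cells, another cell type and sampling at low depth (the last in 3 forms) were chosen only after the results were seen, and the offsets for GC content and gene length were added after the data were seen. The results named first are differences between groups in an effect, each tested directly. The interaction of genotype with amino acid starvation held 1407 genes and that with glucose starvation 3074. The KO effect in normal media differed between the experiments for 2434 genes, and the response to amino acid starvation differed from that to glucose starvation for 8717 genes in WT and 8778 in KO.

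Of the amino acid interaction, Spata33 (2.81), Btg2 (2.35) and Zfp758 (2.24) had the highest log2 differences of the genes named by the rule, and Med12l (-3.96), Hecw2 (-3.88) and Enthd1 (-3.06) the lowest. Btg2, an antiproliferative p53 target, was not called without WT normal media replicate 2 (2.01, adjusted p = 0.0513), and Enthd1 not without KO normal media replicate 2 (-2.48, adjusted p = 0.209).

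Of the glucose interaction, Gjb2 (3.02), Vldlr (2.83) and Igfbp4 (2.30) were highest and Ackr3 (-4.54), Mmp15 (-4.16) and Ppl (-3.57) lowest. Ackr3 had 0 counts in starved KO against 91 in KO, 26 in starved WT and 350 in WT, so its fitted value depends on the prior count. Ppl had 2 against 56, 355 and 567, so its fitted value rests on 2 counts in starved KO. Ackr3 was not called without WT starved replicate 2 (adjusted p = 0.118), KO normal media library a (0.0703), KO starved replicate 1 (0.175) or KO starved replicate 2 (0.154), nor with the DESeq2 Wald test (0.0746).

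Of the difference between experiments, Cldn19 (5.86), Ptprq (5.68) and Sorbs2 (5.48) were highest and C4b (-6.31), Sparcl1 (-5.36) and Rragb (-4.19) lowest. Cldn19 had 332 counts in KO and 92 in WT in the amino acid experiment against 0 and 3 in the glucose experiment, C4b 93 and 490 against 3 and 0, and Sparcl1 217 and 452 against 4 and 0, so the KO effect of these 3 genes was not measured in the glucose experiment and the fitted values depend on the prior count. Cldn19 was not called without amino acid experiment WT replicate 1 (adjusted p = 0.0516) or KO replicate 1 (0.0622), nor without glucose experiment WT library a (0.0857), WT library b (0.23), KO library a (0.123) or KO library b (0.12). Sorbs2 was not called without glucose experiment KO library a (adjusted p = 0.0759) or KO library b (0.0586), and C4b not without WT library a (0.0777), WT library b (0.0986) or KO library a (0.191). Sparcl1 was not called with the DESeq2 Wald test (adjusted p = 0.0509), without amino acid experiment KO replicate 2 (0.051), or without glucose experiment WT library a (0.102), WT library b (0.131), KO library a (0.113) or KO library b (0.0998).

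In normal media the mitosis genes were lower in KO in the amino acid experiment, and the list was not called in the glucose experiment, with a median difference of -1.359. GC content and gene length as the whole cause are argued against, since 100.3% of the median was kept with offsets for both, and so is a single library, since the median lay between -1.077 and -1.534 with each of the 8 normal media libraries left out. Of the 34 DNA replication genes 23 were also lower in the difference. Fewer dividing KO cells or more dividing WT cells in the amino acid experiment, or the reverse in the glucose experiment, may account for the pattern. The values do not tell these apart. The replication list had already been seen lower in KO in the amino acid experiment, so this test adds little of its own. Usf2 was lower in KO in normal media of both experiments (45.3% and 42.1% of the WT level), so its loss alone does not account for a difference between them. Whether the density or age of the cultures or the library preparation changed the KO effect cannot be told apart, because each may differ between the experiments.

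Genes expressed in WT and at the floor in KO (at most 3 counts) numbered 11 in the amino acid and 15 in the glucose experiment, 8 of them in both, and 0 genes were at the floor in WT and expressed in KO. Deletions of chromosome segments that reach the nearest expressed neighbours are argued against as the cause for most of these genes. Of these neighbours 17.3% were lost (9 of 52, 95% interval 8.2 to 30.3). Shorter deletions would leave the neighbours intact, so the test cannot see them and they stay open. Neighbours were counted in each experiment, so those of the 8 genes at the floor in both entered repeatedly. The interval treats all as independent and is too narrow. Sampling at low depth as the cause is argued against for genes with at least 5 CPM in WT of the experiment in which they were not picked. There the ratio of WT to KO counts had a lower 95% bound of at least 8.33 (Zfp521, 637 against 58 counts) in 18 comparisons. The other picked genes were compared only in the experiment in which they were picked. All 26 picks were compared that way, at a level adjusted for all genes tested there. The lowest bound was 13.9 (Arhgdib, 282 against 3 counts), which argues against counting error as the cause for these genes too. The share at the floor in both experiments would not settle it alone. For the genes compared in the other experiment it was 8 of 8 (95% interval 63.1 to 100) and, picked in the glucose experiment, 80% of 10 (44.4 to 97.5). Another cell type in the WT cultures stays open: at most 20% of the members of a list of another cell type expressed in WT were at the floor, but 3 of 5 epithelial markers in the amino acid and 5 of 5 in the glucose experiment were called lower in KO. That share was taken only over lists with at least 3 members over 1 CPM in WT. The epithelial list had 3 such members in the amino acid experiment and 2 in the glucose experiment, so the latter was left out. A difference between the WT and KO lines that arose apart from Usf2 could not be separated from Usf2 loss and stays open, with whole chromosomes shifted in normal media of the amino acid and glucose experiments. The share of genes higher in KO, called or not, was 74.4% and 73.7% on chromosome 10, 66.6% and 72.5% on 8 and 75.2% and 67.3% on 18. It was 38% and 36.3% on chromosome 2, 40% and 39.4% on 5, 34.9% and 38.8% on 13 and 38% and 26.8% on 14. Over all genes the median log2 fold change was -0.007 and -0.006. Some shifts were less alike in the 2 experiments. The share was 44.6% and 25.4% on chromosome 3, and the 6 genes of chromosome Y had a median log2 fold change of -1.032 and -0.15.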

How the results depend on the processing

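The offsets for GC content and gene length were chosen after the data were seen. No named gene was called in opposite directions in any alternative, and neither was any list where lists were tested again. Lists were tested again with DESeq2 size factors, an estimated correlation, the replicate block and 1 library left out, not with the other alternatives. The balance of called genes did turn. Under upper quartile scaling the share higher moved from 68.3% to 42.2% in the amino acid interaction, from 56.1% to 44.5% for KO against WT under amino acid starvation and from 49.9% to 38.6% for the KO response to it. With offsets for GC content and gene length it moved from 50.7% to 59.8% for KO against WT in normal media of the glucose experiment; the cause was not tested. Medians of lists that were not called also changed sign, such as the hydrolases in the amino acid interaction. Camera called 8 to 22 lists per comparison with the preset correlation. With an estimated correlation it called 1 list in the glucose interaction and 0 in each other comparison, where 1 to 10 lists had an unadjusted p under 0.05; the cause was not tested. With 1 library left out, where the lone sample is assumed to vary like the other groups, the count ranged from 4274 to 6845 for KO against WT in normal media of the amino acid experiment, from 304 to 1201 genes and 7 to 12 lists for the amino acid interaction and from 1311 to 2762 for the difference between experiments. With the replicate block the amino acid interaction held 2668 genes, and the DESeq2 Wald test gave 1964 for the glucose interaction; the cause was not tested. The replicate block changed no other count by over 1.5 times. Deviations of samples with the same number correlated at -0.007 to 0.209 over 6 pairs of groups, 3 of them over 0.1, so the samples were not taken as paired; a structure shared by number is not excluded. No block was fitted in the glucose experiment, where the numbers of the 4 normal media columns could not be used, nor in the fits across experiments. Of single genes, 326 results lost and 9 gained a call with 1 library left out against 11145 that did neither, and of single lists 38 lost and 4 gained one against 1390. Genes near the count minimum of 10 limit what this depth can show.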

Other observations

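The offsets for GC content and gene length, and the limit to splits with 2 libraries of each experiment in each group, were added after the data were seen. Under glucose starvation the cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher in KO than in WT in 18 of 20 cases and lower in 0 (19 and 0 adjusted over the list alone; adjusted p = 5.97e-07, and adjusted p = 0.0704 with an estimated correlation). Their starvation response was higher in KO in 13 cases (14 adjusted over the list alone; adjusted p = 1.1e-07, and adjusted p = 0.0644 with an estimated correlation), with Wars, the tryptophanyl-tRNA synthetase, differing by 0.67 ± 0.07 on the log2 scale (SE). Ribosome biogenesis genes had a higher response in KO in 31 of 34 cases, as adjusted over the list alone (adjusted p = 9.97e-13, and adjusted p = 0.114 with an estimated correlation). Their median log2 response was -0.29 in WT and 0.06 in KO, so these genes fell in WT and hardly moved in KO.

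Hox genes, which mark position along the body, were compared between genotypes in each medium. Under amino acid starvation 19 of 32 were lower in KO and 3 higher, as adjusted over the list alone (adjusted p = 0.000103, and adjusted p = 0.535 with an estimated correlation), and under glucose starvation 13 of 31 were lower and 3 higher, as adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.244 with an estimated correlation). In normal media 8 of 32 were lower and 5 higher in the amino acid experiment (8 and 4 adjusted over the list alone; adjusted p = 0.396, and 0.904 with an estimated correlation), and 13 of 31 lower and 6 higher in the glucose experiment, as adjusted over the list alone (adjusted p = 0.229, and 0.604 with an estimated correlation). Tested as an interaction, the response was lower in KO in 3 of 32 cases and higher in 0 in the amino acid experiment (5 and 0 adjusted over the list alone; adjusted p = 0.000177, and adjusted p = 0.813 with an estimated correlation). In the glucose experiment it was lower in 4 of 31 and higher in 1 (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.369, and 0.832 with an estimated correlation). Under starvation Hoxb6 differed by -1.60 ± 0.17 and -1.39 ± 0.12 and Hoxc13 by 0.92 ± 0.12 and 0.81 ± 0.07 (SE).

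The lysosomal hydrolase, lysosomal membrane and v-ATPase genes, 103 in all, had a median log2 fold change of 0.474 in the amino acid and 0.249 in the glucose experiment. Shifts of whole chromosomes as the whole cause are argued against, since at least 87.5% of the median was kept after each chromosome was centred (0.504 and 0.218), and so are GC content and gene length, since at least 110% was kept with offsets for both (0.521 and 0.324). The 18 splits of the 8 normal media libraries with 2 libraries of each experiment in each group are too few for a share under 0.05. Only the real split gave 6445 called genes, and the highest of the others gave 1. All the others mix WT and KO libraries within a group, so genotype differences widen their spread and leave few calls. The contrast therefore does not show what groupings without any effect would give. Whether Usf2 loss or a difference between the lines that arose apart from it raised these genes was not tested.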
